A study of Homo sapiens with 6 samples.

How the data were processed

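RNA immunoprecipitation followed by sequencing (RIP-seq) was carried out in 2 established human triple-negative breast cancer cell lines, BT549 and MDA-MB-231, with 3 libraries per line. The antibody is labelled EFP, an alias of TRIM25, the RING-type ubiquitin ligase and RNA-binding protein that the series names as its subject. Per the labels' protocols, RNA bound to the protein was recovered with an EZ-Magna RIP kit, ribosomal RNA was depleted and stranded total RNA libraries were made. Per the submitters' processing notes, BWA, GATK and MACS2 were used. Their versions, settings and order, the genome build and the control set used for peak calling are not given in the sources used here. Input or non-specific antibody libraries were not analysed here, so a peak is a region called by the authors and not a measured enrichment over a control held here.

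The authors deposited 1 peak list per library, called separately in each, with a chromosome, a start, an end and a score for every peak. The deposited score was taken as a linear fold enrichment (a ratio) from its values. In 5 of the 6 lists the 8 commonest scores of the narrowest peaks lay on an evenly spaced ladder within a tolerance of 0.01, as a pileup plus 1 divided by a background plus 1 would give. In BT549 replicate 1 none of the 8 did, so the unit rests on the other lists there. Every peak was listed on the same strand, so strand was not used. Scores were used to describe, rank or filter peaks within a list, and are printed as each list's own values, with no mean over lists. In every list the smallest gap between neighbouring peaks was 4 times the narrowest peak plus 1 base, and the narrowest peak differed between lists. The lists therefore differ in how finely nearby peaks were kept apart. Read numbers are unknown from these files, and no interval or detection limit that needs them is given.

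The files name no genes. Their contig names follow the older gl-numbered style, 1 contig is a decoy, and peaks on chromosome 1 reach position 249236718, past the last gene of the RefSeq table held here, which is for assembly GRCh38.p14. That table was therefore not used to place genes, and no coordinate was converted. Positions are those of the deposited files, written from 1, on a build not given in the sources used here. The gene-based results planned before the data were examined (annotation classes, genes with peaks, 15 gene lists and named genes, TRIM25 among them) were not run. After the files were seen, the same questions were asked of genomic regions, and these region-based definitions were chosen after the data were examined. The relations of list measures to the narrowest peak width were also added then. A 10 kb window counted as occupied in a library when it held at least 1 bp of a peak. Windows took the place of genes in the overlap tests, windows occupied in all 3 libraries of a line and none of the other took the place of line-restricted genes, and 1 Mb bins served for a test across the genome.

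Peak numbers, covered length and shares per chromosome were compared between lines with exact two-sided permutation tests. With 3 libraries against 3 the smallest p is 0.1. Overlap of peak lists was measured as the Jaccard index of covered bases (bedtools 2.31.1) for the 15 pairs of libraries. The mean of the 6 within-line pairs minus the mean of the 9 between-line pairs was tested one-sided over the 10 splits of the 6 libraries into 3 and 3. The overlap of windows between lines was tested with Fisher's exact test among windows occupied in at least 1 library, with the overlap of independent lists beside it. Neighbouring windows are not independent, so this test describes these lists and does not replace a test between libraries. For the 1 Mb bins, the number of occupied windows per bin and library was taken as log2(windows + 1), quantile normalised and fitted with limma 3.58.1 in R 4.3.3 (eBayes with a trend), keeping bins with a mean of at least 5 occupied windows. Bins with a Benjamini-Hochberg adjusted p under 0.05 were called. Differences are on the log2(windows + 1) scale and understate changes of bins with few windows. Bins were also simulated from the mean occupancy and library totals of these data, with binomial noise and an added spread that was set and not estimated. The fit recovered 25.0% of 100 bins whose odds of occupancy were changed by a factor of 2. It recovered 92.0% of 100 changed by a factor of 4, with 1 false call among 2258 unchanged bins. Real libraries of a line can differ more, as with 7, 61 and 70 windows in BT549 for chromosome 5 at 12000001. These rates may therefore not hold for the real lists. The window counts recovered 200 of 200 planted windows among 20000, which checks the counting only.

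The rule for named items, written for genes, was applied to windows. For each line, for all 6 libraries together and for windows restricted to a line, it took the 10 with the highest mean percentile of their best peak by score. For bins, the 10 called bins with the largest difference in each direction and with no overlap between the libraries of the lines were named. Stretches are runs of neighbouring windows without a peak in any library of the other line, ranked by the number of windows occupied in all 3 libraries of the line. Alternatives were the upper 50% of each list by score, the 67793 best peaks of each list, removal of unplaced contigs and the mitochondrial chromosome, each library left out in turn, a replicate block, other overlap measures, 1 kb and 100 kb windows, other scalings and pseudocounts, and lists in which peaks 1108 bp or less apart were rejoined and pieces narrower than 277 bp then dropped. The last of these gives every list the joining distance and narrowest width of the coarsest one, and each of these changes was also made alone for peak number. Densities per Mb were also taken over the span from the first to the last peak of a chromosome. Whether libraries of a line came from separate cultures is not stated in the labels, so p-values measure only the spread between these libraries, which may be technical. Replicate numbers were not used to pair libraries. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.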

Results

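The series asked which RNAs TRIM25 binds in 2 cell lines of triple-negative breast cancer. BT549 and MDA-MB-231 are established lines with a mesenchymal-like appearance, and each gave 3 immunoprecipitated libraries with its own peak list. The BT549 lists held 67793, 233567 and 380446 peaks in replicates 1, 2 and 3, and the MDA-MB-231 lists held 261361, 242572 and 321357. The peaks covered 91.0, 77.3 and 38.7 Mb in BT549 and 76.2, 79.2 and 43.4 Mb in MDA-MB-231. The median of the score the authors gave each peak, whose unit they did not state and which was taken as a fold enrichment from its values, was 2.10, 3.10 and 3.08 in BT549 and 3.17, 3.08 and 3.13 in MDA-MB-231. In BT549 replicate 1 the values did not show this unit, and its folds below rest on the other lists. Peaks lay in 157094 of the genome's 10 kb windows in at least 1 library, and 40662 of these held a peak in 1 library only. RNA abundance and DNA copy number were not measured here, and the control used for peak calling is not given. Differences between the lines reported below therefore cannot be told apart from differences in RNA abundance or copy number.

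Among chromosomes 1 to 22 and X, peaks were densest on chromosome 19, with 49.9 ± 6.31 occupied 10 kb windows per Mb (SD, n = 6) over the span from position 1 to the last peak, and this chromosome ranked first in 6 of 6 libraries. Chromosome 17 followed with 43.0 ± 6.80. Chromosomes 19 and 17 are rich in genes. Among the low densities were 19.5 ± 4.55 on chromosome X and 19.3 ± 4.07 on chromosome 21. The order depended on the span for chromosomes whose short arm held no or few peaks. Over the span from the first to the last peak, chromosome 13 had 22.8 windows per Mb, chromosome 21 had 24.1 and chromosome X had 19.6. Chromosome 22 went from 29.8 to 43.5, beside 43.0 on chromosome 17, while chromosome 19 still ranked first in 6 of 6 libraries. Among the windows with a peak in all 6 libraries, those whose best peaks ranked highest within their lists lay in a few places. On chromosome 13 they were 23930001 to 23940000, 23940001 to 23950000, 24040001 to 24050000 and 20640001 to 20650000. Their best folds, each on its own list's scale, lay between 7.69 and 12.2 in the first, 8.53 and 12.9 in the next, 7.07 and 16.9 in the third and 5.998 and 15.9 in the last. On chromosome 21, 4 windows between 32500001 and 32560000 had best folds from 4.06 to 20.2. The remaining windows were chromosome 1 at 228270001 to 228280000, with 6.91 to 13.2, and chromosome 18 at 23870001 to 23880000, with 5.86 to 13.9.

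The first comparison was the number of peaks per library in the lines. BT549 had 227269 ± 156422 peaks and MDA-MB-231 had 275097 ± 41149 (SD, n = 3 each), a difference smaller than the spread between BT549 libraries (exact permutation test, two-sided, p = 0.7, where the smallest possible is 0.1). Covered length was 69.0 ± 27.2 Mb in BT549 and 66.3 ± 19.8 Mb in MDA-MB-231 (exact permutation p = 0.9). Leaving out BT549 replicate 1, which had the fewest peaks, turned the difference of -47828 peaks into 31910.

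Peak number followed the narrowest peak of each list. This relation was not planned and was tested on the lists in which it was seen. A list that keeps nearby peaks apart more finely tends to hold more of them, so the p-values describe these 6 lists only. The narrowest width was 277, 65 and 17 bp in BT549 replicates 1, 2 and 3 and 56, 62 and 21 bp in MDA-MB-231. The list with the wider narrowest peak had fewer peaks in every pair of libraries (Spearman's rho = -1, exact permutation p = 0.00278, adjusted 0.0111 over 4 relations; Pearson's r of the log10 values = -0.947, exact permutation p = 0.00139, adjusted 0.00556). Without BT549 replicates 1 and 3, the libraries farthest from the median width, r was -0.976, and rho was -1 within each line. Covered length rose with the same width (rho = 0.943, exact permutation p = 0.0167, adjusted 0.0333; r = 0.897, exact permutation p = 0.00278, adjusted 0.00556; r = 0.995 without the same libraries). The number of occupied 10 kb windows had no such relation (rho = -0.143, exact permutation p = 0.803, adjusted 0.803; r = -0.763, exact permutation p = 0.140, adjusted 0.140), and without the same libraries its r was 0.955. After all lists were rejoined at the gap and width of the coarsest list, BT549 had 64699 ± 2887 peaks and MDA-MB-231 had 63288 ± 4672 (SD, n = 3 each, exact permutation p = 0.7), and the rejoined number was not related to the width past the threshold (rho = 0.714, exact permutation p = 0.136, adjusted 0.181; r = 0.811, exact permutation p = 0.0597, adjusted 0.0796; r = 0.949 without the same libraries).

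**Figure D1:**
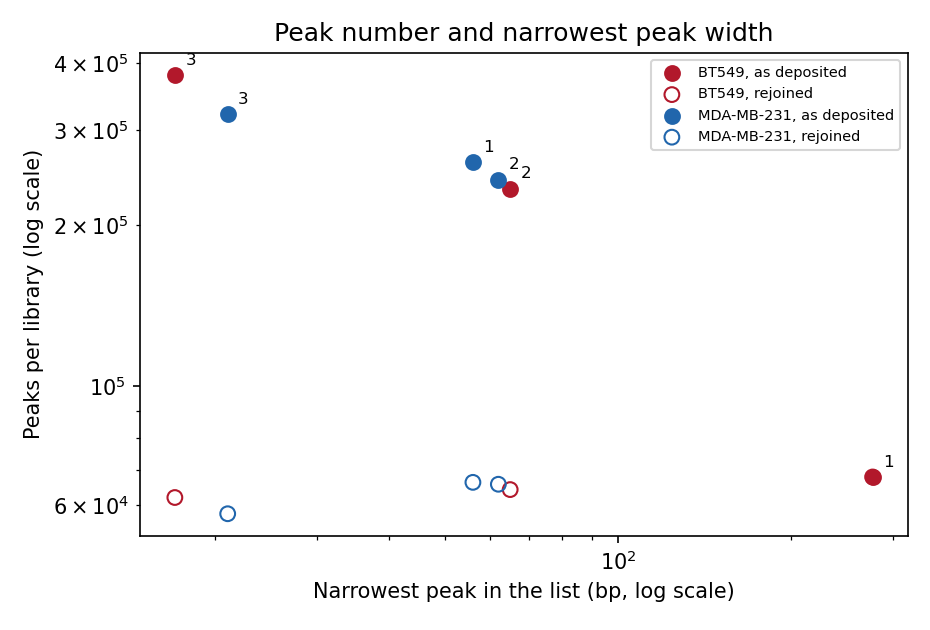
Number of peaks per library (log scale) against the width of the narrowest peak in its list (bp, log scale), as deposited (filled) and after all lists were rejoined at one gap and width (open). Each point is 1 library, numbered by replicate, with BT549 in red and MDA-MB-231 in blue. Deposited numbers run from 67793 to 380446 and rejoined numbers from 57902 to 67793.

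The second comparison asked whether libraries of a line shared more of their peaks with each other than with the other line. The Jaccard index of covered bases was 0.258 ± 0.0562 among the BT549 libraries and 0.297 ± 0.0513 among the MDA-MB-231 libraries (SD, n = 3 pairs each), against 0.248 ± 0.0377 between lines (n = 9 pairs). Within-line pairs were higher by 0.0296 on average, the highest of the 10 splits of the libraries (exact permutation test, one-sided, p = 0.1, the smallest possible). The ranges overlapped, from 0.214 to 0.321 within BT549 and from 0.208 to 0.302 between lines. The index also differed with the narrowest width of the lists. Pairs with a replicate 3 list (narrowest peaks of 17 and 21 bp) ran from 0.208 to 0.271, and the other pairs from 0.267 to 0.356. BT549 replicate 2 had 0.237 with BT549 replicate 3, but 0.295 and 0.302 with MDA-MB-231 replicates 1 and 2. In rejoined lists the within-line excess was 0.0423 (exact permutation test, one-sided, p = 0.1). For 10 kb windows the index was 0.561 ± 0.0124 within MDA-MB-231, above every between-line pair, of which the highest was 0.491. Within BT549 it was 0.458 ± 0.0657, beside 0.456 ± 0.0429 between lines, and BT549 replicate 1 lowered both. BT549 replicates 2 and 3 had an index of 0.534 with each other, above every between-line pair. Replicate 1 had 0.424 and 0.418 with them, and 0.397 to 0.404 with the MDA-MB-231 libraries.

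**Figure D2:**
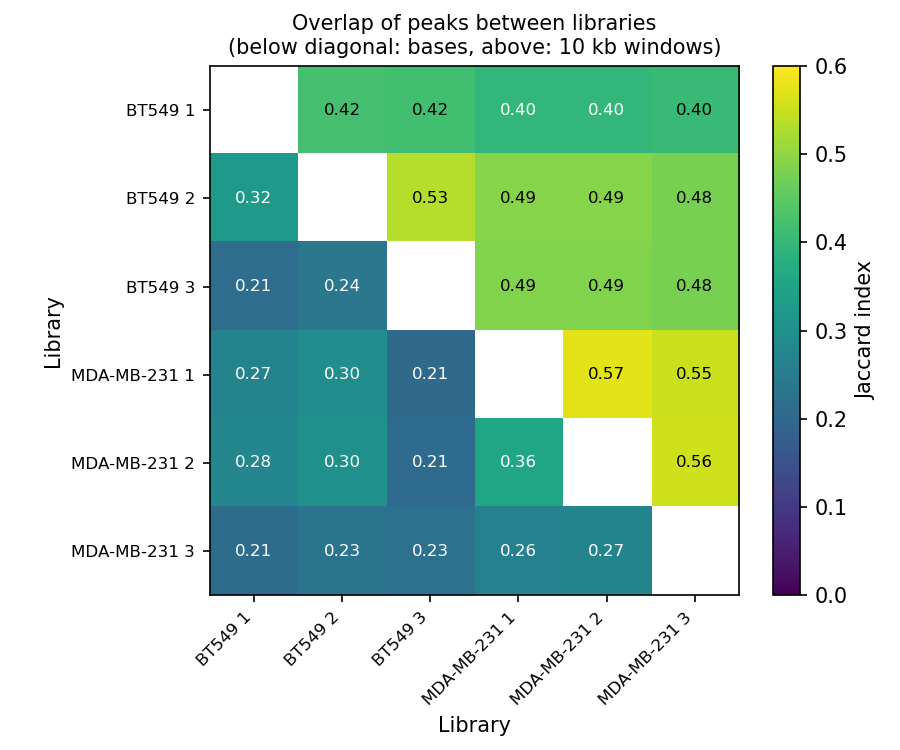
Jaccard index for each pair of libraries, as colour and number, for covered bases (below the diagonal) and for occupied 10 kb windows (above the diagonal). The 3 MDA-MB-231 pairs have window values from 0.551 to 0.575, and the between-line pairs reach at most 0.491.

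The third comparison was between the regions occupied throughout each line. All 3 BT549 libraries had a peak in 36463 windows of 10 kb and all 3 MDA-MB-231 libraries in 53070. These lists shared 23591 windows, 64.7% of the BT549 windows and 44.5% of the MDA-MB-231 windows. Independent lists of these sizes would share 12318, so the overlap was 1.92 times that number (odds ratio 5.67, 95% interval 5.53 to 5.81 by Fisher's exact test over windows, which are not independent replicates). In the alternatives this ratio ran from 1.37 with at least 2 of 3 libraries to 3.70 against a background of all windows. Of the windows occupied in all 3 BT549 libraries, 96.5% had a peak in at least 1 MDA-MB-231 library, and 89.9% the other way round. In 1264 windows all 3 BT549 libraries and no MDA-MB-231 library had a peak, and in 5341 windows the reverse held. The excess on the MDA-MB-231 side depended on BT549 replicate 1 and on lists longer than the shortest. Replicate 1 occupied 49274 windows where the other 5 libraries occupied 86996 to 94708. Without it, 6081 windows were restricted to BT549 and 5995 to MDA-MB-231, where BT549 windows needed only both remaining libraries and MDA-MB-231 windows still all 3. With the upper 50% of each list by score the excess stayed, with 1297 against 3506. With the 67793 best peaks of each list the direction turned, with 1571 windows restricted to BT549 and 1241 to MDA-MB-231, and in rejoined lists the numbers were 2015 and 3254. The cut to 67793 peaks kept the whole list of BT549 replicate 1, down to a score of 1.00007, and only the best-scoring part of the others.

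The windows whose best peaks ranked highest within the BT549 lists were chromosome 3 at 47260001 to 47270000, with best folds of 11.5 to 19.1 in the 3 libraries, chromosome 21 at 32570001 to 32580000, with 9.19 to 27.1, and chromosome 9 at 16710001 to 16720000, with 10.3 to 16.98. The first had a peak in 3 MDA-MB-231 libraries, the next in 2 and the last in none. The other 7 BT549 windows had best folds from 7.30 to 16.2. The highest-ranking windows of MDA-MB-231 were chromosome 6 at 2250001 to 2260000, with best folds of 20.9 to 22.3, and chromosome 7 at 127920001 to 127930000, with 13.4 to 21.5. Among the 8 others, 3 lay on chromosome 18 between 44360001 and 44430000, with 10.9 to 24.7. Chromosome 9 at 20790001 to 20800000 had 12.5 to 19.4, and chromosome 7 at 135010001 to 135020000 had 14.5 to 18.02. Of the 10 MDA-MB-231 windows, the last named had a peak in 1 BT549 library and the other 9 in 2 or 3.

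Among windows restricted to BT549, those ranking highest after chromosome 9 at 16710001 were chromosome 4 at 174440001 to 174450000, with best folds of 7.97 to 10.9 in the 3 libraries, and chromosome 4 at 75000001 to 75010000, with 6.59 to 9.62. Of the 10 named, 4 lay on chromosome 9 (16700001, 16710001, 21530001 and 22090001), and chromosomes 11, 4 and 2 gave a pair each. The chromosome 2 windows (70920001 and 70930001) adjoin and had the same best fold in BT549 replicates 2 and 3 (20.8 and 5.30). They may hold the same peaks. Among windows restricted to MDA-MB-231, the leading ones were chromosome 18 at 8170001 to 8180000, with best folds of 11.5 to 16.1, chromosome 4 at 83670001 to 83680000, with 9.88 to 18.96, chromosome 5 at 114890001 to 114900000, with 10.1 to 18.1, and chromosome 18 at 7940001 to 7950000, with 11.6 to 14.96. Folds are the authors' scores on each list's own scale, and they were not compared between lines.

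Stretches were runs of neighbouring windows without a peak in one line, ranked by how many of their windows all 3 libraries of the other line occupied. In several leading stretches most windows were not occupied in all 3. In MDA-MB-231 the longest by windows occupied in all 3 libraries was chromosome 18 from 7570001 to 7960000, where 39 of 39 windows had a peak in every MDA-MB-231 library and none had a peak in BT549. It was followed by chromosome 20 from 58710001 to 58950000, with 21 of 24 windows, chromosome 12 from 3410001 to 3940000, with 19 of 53, and chromosome 7 from 131350001 to 131580000, with 19 of 23. In BT549 the leading stretches were chromosome X from 35590001 to 36250000, with 21 of 66 windows occupied in all 3 libraries, chromosome 9 from 8210001 to 9090000, with 17 of 88, and chromosome 9 from 21970001 to 22130000, with 14 of 16. Of the 10 leading BT549 stretches, 5 lay on chromosome 9. Those starting at 20870001, 21300001 and 21970001 lay close together, parted by scattered windows with an MDA-MB-231 peak in some libraries. They may be pieces of 1 region and are not independent. A further MDA-MB-231 stretch on chromosome 18, from 8080001 to 8250000, had 15 of 17 windows occupied in all 3 libraries. It was parted from the one starting at 7570001 by windows at 7960001 and 8070001, each with a peak in 1 BT549 library. These stretches are therefore not independent. There were 32 BT549 and 155 MDA-MB-231 stretches with at least 5 windows occupied in all 3 libraries. The numbers were 146 against 163 without BT549 replicate 1 and 28 against 33 with the 67793 best peaks of each list, but the imbalance stayed with the upper 50% of each list by score, 23 against 94, and in rejoined lists, 47 against 96. Without BT549 replicate 1, BT549 windows needed only both remaining libraries and MDA-MB-231 windows still all 3, so the criteria of the lines were unlike. Among the 20 leading stretches, the number of such windows moved by over 1.5 times in 12 with the upper 50% of each list by score, in 19 with the 67793 best peaks and in 14 with rejoined lists. Leaving out BT549 replicate 1 raised it by over 1.5 times in 4 BT549 stretches, among them chromosome 9 from 8210001 to 9090000, where 29 windows were then occupied in both remaining libraries.

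**Figure D3:**
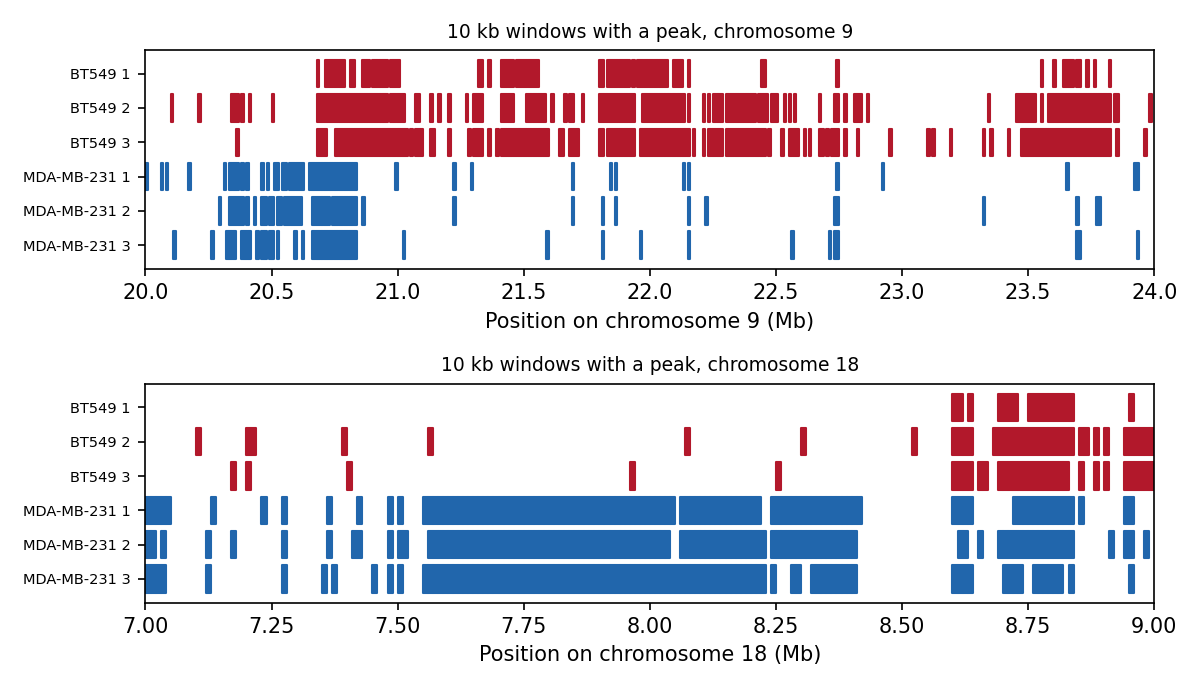
Map of 10 kb windows with a peak (bars) in each library along chromosome 9 from 20 to 24 Mb and chromosome 18 from 7 to 9 Mb, with position in Mb on the horizontal axis, BT549 in red and MDA-MB-231 in blue. On chromosome 18 the MDA-MB-231 libraries fill 39 of 39 windows between 7570001 and 7960000, which hold no BT549 peak.

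At the scale of 1 Mb, 203 of 2458 bins differed in occupancy between the lines, 80 of them higher in BT549 and 123 higher in MDA-MB-231 (limma, Benjamini-Hochberg adjusted p under 0.05). Whether a called bin reflects binding, RNA abundance or copy number was not tested. Over all 2458 bins, the unscaled window numbers of the lines did not overlap in 513, 20.9% of bins where chance gives 10%. BT549 was higher in 44 of these and MDA-MB-231 in 469, and BT549 replicate 1 had the fewest windows in total. Among the 203 called bins, the unscaled numbers did not overlap in 159, and in the rest they overlapped. The 80 calls higher in BT549 outnumber the 44 bins. Some of these calls therefore lacked every BT549 library above every MDA-MB-231 library before scaling. The excess of calls on the MDA-MB-231 side went when an MDA-MB-231 library was left out, with 54 bins higher in BT549 against 55 without replicate 1, 35 against 29 without replicate 2 and 53 against 51 without replicate 3. It widened without BT549 replicates 2 and 3, to 35 against 93 and 36 against 104. Without BT549 replicate 1 it stayed, with 69 against 112, and with total scaling the numbers were 38 and 89. The largest difference was chromosome 5 at 12000001 to 13000000, with 46.0 ± 34.1 occupied windows in BT549 and 0.667 ± 0.577 in MDA-MB-231 (SD, n = 3 each), a log2 difference of 4.77 ± 0.57 (SE, limma adjusted p = 0.00188). Within BT549 this bin held 7 windows in replicate 1, 61 in replicate 2 and 70 in replicate 3. Chromosome 9 at 28000001 to 29000000 had 51.3 ± 41.0 windows against 1 ± 1.73, and chromosome 5 at 168000001 to 169000000 had 43.3 ± 16.7 against 3 ± 3.61 (log2 differences 4.68 and 4.11, limma adjusted p = 0.00772 and 0.00570). The BT549 libraries were closer together in chromosome 9 at 21000001 to 22000000, with 47.7 ± 12.5 against 4.33 ± 0.577 windows (log2 difference 3.64 ± 0.30, limma adjusted p = 0.000329), in chromosome 9 at 8000001 to 9000000, with 30.7 ± 11.0 against 1.67 ± 0.577 (3.79 ± 0.37, limma adjusted p = 0.000845), and in chromosome X at 36000001 to 37000000, with 37.7 ± 7.77 against 3 ± 2 (3.71 ± 0.36, limma adjusted p = 0.000845). The bins that follow on chromosome 9, singled out after their values were seen, were also higher in BT549. The bin at 22000001 to 23000000 had 41 ± 22.7 windows against 4.33 ± 0.577 (log2 difference 3.34 ± 0.36, limma adjusted p = 0.00127), and the bin at 23000001 to 24000000 had 31 ± 17.6 against 3.33 ± 0.577 (3.16 ± 0.38, limma adjusted p = 0.00192). In chromosome 13 at 84000001 to 85000000, BT549 had 18 ± 16.1 windows and the MDA-MB-231 libraries had 0 each (limma adjusted p = 0.00888). The BT549 libraries held 1, 33 and 20 windows there, and this bin lost its call with total scaling (limma adjusted p = 0.0527).

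Among bins higher in MDA-MB-231, chromosome 18 at 7000001 to 8000000 had 56.3 ± 0.577 occupied windows against 3 ± 2.65 in BT549 (SD, n = 3 each; log2 difference -3.75 ± 0.30 SE, limma adjusted p = 0.000329). Chromosome 12 at 74000001 to 75000000 had 40 ± 3.46 against 2 ± 2.65 (-3.64 ± 0.62, limma adjusted p = 0.00880), and chromosome 12 at 5000001 to 6000000 had 35.3 ± 12.5 against 2.33 ± 4.04 (-3.53 ± 0.62, limma adjusted p = 0.00888). Chromosome 6 at 9000001 to 10000000 had 21.7 ± 5.13 against 0.333 ± 0.577 (-3.52 ± 0.60, limma adjusted p = 0.00880), and chromosome 3 at 168000001 to 169000000 had 45 ± 7.55 against 4 ± 3 (-3.04 ± 0.34, limma adjusted p = 0.00141). The other 5 named bins, on chromosomes 3, 5, 6 and 7, had log2 differences from -2.75 to -3.19. Fewer bins were called in shorter lists. With the upper 50% of each list by score 3 bins were higher in BT549 and 5 in MDA-MB-231, and with the 67793 best peaks of each list limma called 0, with 268 bins at an unadjusted p under 0.05. With the upper 50%, 17 of the 20 named bins lost their call, while 18 stayed within 1.5 times of their log2 value and 20 kept their sign, and the median SE went from 0.56 to 0.93 on the log2 scale. With a pseudocount of 5 they stayed within 1.5 times in 8 of 20, and their median size went from 3.64 to 2.32.

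**Figure D4:**
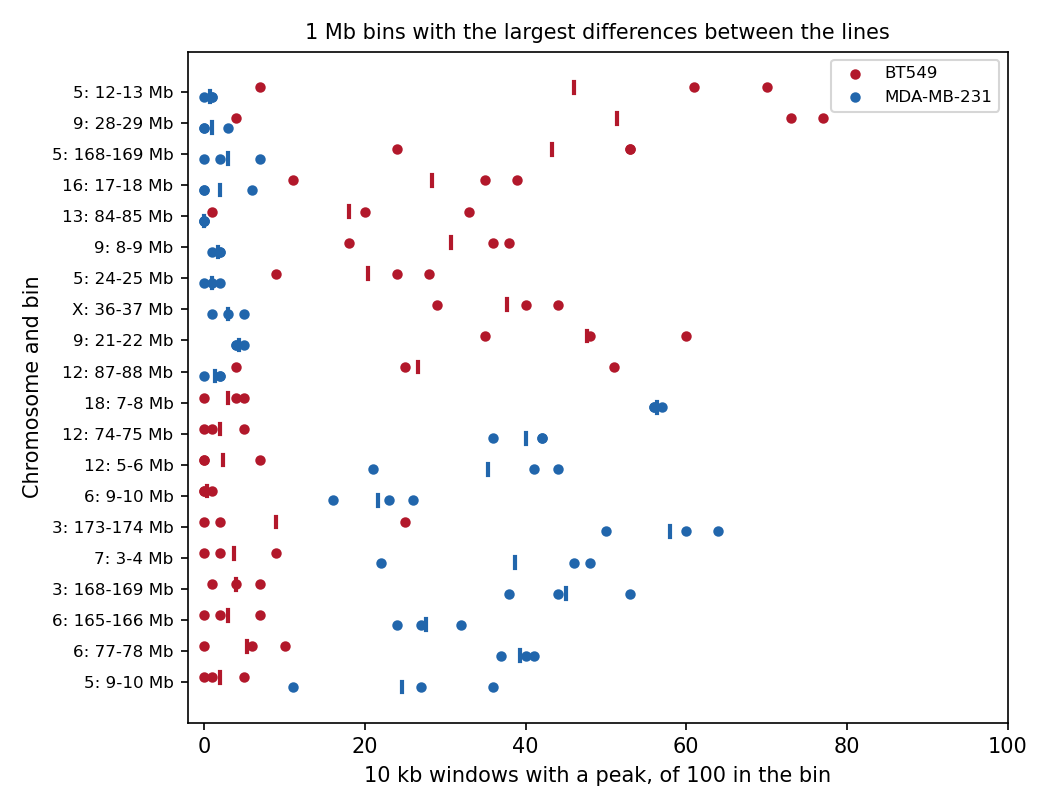
Occupied 10 kb windows per 1 Mb bin (horizontal axis, of 100) in each library for the 10 called bins with the largest difference in each direction. Points are libraries and short vertical lines are means of 3, with BT549 in red and MDA-MB-231 in blue. In chromosome 18 at 7 to 8 Mb the MDA-MB-231 libraries hold 56 or 57 windows and the BT549 libraries 0, 4 and 5.

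The share of each library's peaks on whole chromosomes was compared as well. On 11 of 23 chromosomes the libraries of the lines did not overlap, where chance gives 10% of chromosomes. BT549 had the higher share on chromosomes 8, 9, 13, 16, 19 and 22, and MDA-MB-231 on chromosomes 2, 4, 7, 11 and 12. Chromosome 9 held 5.002 ± 0.0971% of BT549 peaks and 4.39 ± 0.136% of MDA-MB-231 peaks, and chromosome 13 held 2.56 ± 0.126% and 2.20 ± 0.0581% (SD, n = 3 each). Chromosome 11 held 4.45 ± 0.0931% and 5.30 ± 0.0863%, and chromosome 7 held 4.95 ± 0.211% and 5.62 ± 0.0428%. Each of these 11 had an exact permutation p of 0.1, the smallest possible, and an adjusted value of 0.209 over 23 chromosomes, so none passed on its own.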

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

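The rejoined lists, window sizes, scalings, spans, pseudocount, bin filter, contigs in bins and all alternatives for chromosomes and stretches were chosen after the data were examined. Alternatives for genes, annotation classes and gene lists were not run, since no annotation of the files' build was held. The 67793 best peaks give no peak number. Depth is unknown, so what it limits was not measured.

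The difference in peaks per library (BT549 minus MDA-MB-231) turned from -47828 to 1410 in the rejoined lists. It ran from -124417 to 31910 (without BT549 replicate 1) with a library left out. The excess of within-line over between-line Jaccard values kept its direction in every alternative run, but other splits reached it (exact permutation p = 0.4) at 0.00409 in the 67793 best peaks and at 0.0127 with 50% reciprocal overlap, and p ran from 0.1 to 0.3 without a library.

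Windows occupied in all 6 libraries numbered 2014 in the upper 50% of peaks, 324 in the 67793 best, 12842 in rejoined lists, 60500 with at least 2 of 3 libraries and 10716 at 100 kb. Their excess over independent lists was 2.95 at 1 kb and 3.70 against a background of all windows. Windows restricted to BT549 numbered 1571 in the 67793 best, 2015 in rejoined lists, 5378 at 1 kb and 156 at 100 kb, and 1529 to 6081 without a library (6081 without BT549 replicate 1, 2134, 2051 and 2046 without MDA-MB-231 replicates 1, 2 and 3). Those restricted to MDA-MB-231 numbered 3506 in the upper 50%, 1241 in the 67793 best, 3254 in rejoined lists, 15205 at 1 kb and 537 at 100 kb, and 5995 to 9009 without a library (9006 and 9009 without BT549 replicates 2 and 3, 8736 without MDA-MB-231 replicate 3). Stretches with at least 5 windows numbered 35 to 146 in BT549 without a library (146 without BT549 replicate 1). In MDA-MB-231 they numbered 94 in the upper 50%, 33 in the 67793 best and 96 in rejoined lists, and 163 to 285 without a library (285 and 278 without BT549 replicates 2 and 3, 260 without MDA-MB-231 replicate 3).

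Bins higher in BT549 numbered 38 with total scaling, 3 in the upper 50% of peaks, 0 in the 67793 best and 130 at 1 kb, and 35 to 69 without a library. Bins higher in MDA-MB-231 numbered 5 in the upper 50% and 0 in the 67793 best, and 29 to 112 without a library. By limma, 336 and 268 bins had an unadjusted p under 0.05 in these settings, against 621. With total scaling 29.9% of the called bins were higher in BT549, against 39.4%. The cause of changes in these counts was not tested. No named bin changed sign. Of the 20, 17 lost their call in the upper 50%, 13 in the 67793 best (7 had too few windows there, and 5 in rejoined lists), 1 with total scaling, and those at 173000001 on chromosome 3 and 9000001 on chromosome 5 without a library. Their log2 values stayed within 1.5 times in 18 of 20 in the upper 50% and in 11 of 13 in the 67793 best, where the median SE went from 0.50 to 1.10. In the upper 50% of peaks, 7 chromosomes had libraries that did not overlap between lines.

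Window deviations of libraries with the same replicate number correlated at 0.00794, 0.00326 and 0.00810, above those with other numbers but under 0.1. In list measures the replicate 3 lists of both lines were alike. They had the smallest narrowest widths, 17 and 21 bp, and the smallest covered lengths, 38.7 and 43.4 Mb. The replicate 1 lists were not alike, with narrowest widths of 277 and 56 bp. With the replicate block, 94 bins were higher in BT549 and 155 in MDA-MB-231, and 187 of the 203 were called in both fits. With that block the sign-flip permutation gave p = 0.75 for the -47828 peaks. Among the 4 splits that part the numbers, p was 0.25, the smallest possible, for the Jaccard difference of 0.0296 and for the 6605 restricted windows.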

Other observations

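The splits of the libraries and the lists cut to 67793 peaks were planned for genes and used here for regions, and the other tests in this part were chosen after the results were seen. Of 10 unplaced or decoy contigs with a mean of at least 5 peaks per library, 2 had libraries that did not overlap between the lines, where chance gives 10%. The chromosome 7 contig gl000195 held 55, 56 and 82 peaks in the MDA-MB-231 libraries and 0, 0 and 5 in the BT549 libraries (exact permutation p = 0.1, the smallest possible for n = 3 each). The chromosome 4 contig gl000194 went the other way, with 10, 18 and 71 peaks in BT549 and 2, 2 and 0 in MDA-MB-231 (exact permutation p = 0.1, and adjusted 0.5 for both over the 10 contigs). The other 8 contigs overlapped (exact permutation p from 0.4 to 1). On the mitochondrial chromosome each library had 2 to 6 peaks. The 80 bins higher in BT549 included 14 on chromosome 9 where 3.65 were expected, and the 123 bins higher in MDA-MB-231 included 15 on chromosome 12 where 6.10 were expected (permutation p = 0.0293 and 0.0283 by circular shifts of the bins, adjusted 0.674 over 46 tests for both), so neither passed the correction.

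The number of peaks differed 5.61-fold between the libraries. After all lists were rejoined at one gap and width the ratio of the highest to the lowest number was 1.17, which is consistent with the joining distance and narrowest width of the lists together as the source of most of the difference. Joining alone left a ratio of 2.45 and the minimum width alone 2.86. Each thus removed part of the difference, and neither alone accounts for all of it. Joining alone brought the other 5 lists from between 233567 and 380446 peaks to between 154419 and 166299. BT549 replicate 1 stayed apart at 67793. The number of reads stays open, and no biological explanation was tested. Among the 5 lists whose scores form a ladder the background pileup per base differed by a factor of 1.10, but a caller that scales libraries to one depth would give this at any number of reads.

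Windows restricted to MDA-MB-231 outnumbered those restricted to BT549 by 4.23 to 1, by 1.61 to 1 in rejoined lists and by 0.790 to 1, the opposite direction, with the 67793 best peaks of each list. That last cut left the BT549 replicate 1 list whole and shortened the others. In comparisons of 2 libraries against 2 without BT549 replicate 1 the mean ratio was 1.06, and with it the ratio ran from 4.73 to 5.63, so the excess may come from the narrow reach of that list. Whether the number of reads explains that reach stays open, since 0 of the 8 commonest scores of its narrowest peaks lay on a ladder and its background could not be read. The restricted windows of both lines together numbered 6605, and the highest of the other splits gave 2012, while the called 1 Mb bins numbered 203 and the highest other split gave 0. In each case 1 of the 10 splits gave as large a number, and 10 splits are too few to exclude chance.

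On chromosome 9, peaks of MDA-MB-231 stopped at position 20840000 while those of BT549 went on. In the 160 kb before that edge the MDA-MB-231 libraries occupied 97.9% of the windows, and in the 160 kb after it 4.17%, where BT549 occupied 83.3% and 89.6%. The edge and the segment were picked from these same values, so the drop restates that choice and tests no explanation. Over the whole list, the MDA-MB-231 libraries occupied 83.7% of the windows that held a peak in every BT549 library. Such windows therefore showed no general shortage of MDA-MB-231 peaks. Between the edge and 24 Mb the MDA-MB-231 libraries occupied 8.59% of the 66 such windows. A loss of the segment in MDA-MB-231, a line known to lack CDKN2A on the short arm of chromosome 9, may underlie the drop. Similar absences lay on chromosome 9 outside the segment. The bin at 26000001 held 36, 30 and 36 windows in the MDA-MB-231 libraries, but that at 28000001 held 3, 0 and 0, against 4, 77 and 73 in BT549. The bin at 8000001 held 2, 2 and 1 against 18, 38 and 36. Between the edge and 24 Mb MDA-MB-231 occupied 2.52% of the windows without a BT549 peak, and 9.72% of such windows genome-wide. That low value also follows from how the segment was picked. Some MDA-MB-231 peaks remained, 2 windows (22150001 and 22740001) had one in every library, and without DNA data or gene positions a loss cannot be told apart from a segment not transcribed in MDA-MB-231, a difference between the lines that was not tested.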
